A study of Mus musculus with 3 samples.

How the data were processed

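The data are 3 single-cell RNA-seq libraries of mouse pancreatic islet cells, 1 each from WT, ASF-KO and SC35-KO mice 9 months old. Per the labels' protocols, collagenase was perfused through the bile duct, islets were picked by hand under a stereomicroscope, dissociated with trypsin and sieved, and libraries were made with a Chromium 3' v3 kit. The deposited files of each library hold UMI counts per gene and barcode for 32285 genes, as whole numbers with no normalization. The submitters' processing notes name Cell Ranger 5.0.0, STAR, Seurat and mm10, without saying what each was used for. The lowest totals per barcode in the deposited counts were 500, 557 and 500 UMIs, so barcodes with fewer were not in the files. The WT group was taken from the sample's title and both KO groups from the genotype label.

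Barcodes with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept, which removed 978 in WT, 5095 in the library labelled ASF-KO and 2234 in the library labelled SC35-KO. Doublets were marked with Scrublet in each library at its automatic threshold (375, 363 and 941 cells, or 4.04%, 4.91% and 8.05%) and removed. Counts were scaled to the cell total and log-transformed, 2000 variable genes were chosen across libraries, and the 3 libraries were clustered together without batch integration, on 30 principal components and a graph of 15 neighbours with Leiden at resolution 1.0. Clusters were called X-like from marker genes of 24 cell types fixed before the data were examined. A cluster was left unnamed if it rested on under 3 detected markers, if more markers of another type were among its 10 leading genes, or if its median UMI count was under 0.333 of its libraries' with no marker of its own among them. The way markers were scored, the minimum score of 0.4, the need for 3 detected markers, the merging of B and plasma cells, and the naming of clusters made in each library alone by markers scaled over all libraries were set after the clusters were seen. Tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, statsmodels 0.14.6 and matplotlib 3.10.9.

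Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals and their differences Newcombe intervals. Within each class of at least 100 cells per library, UMIs were summed per library and scaled to a common total (CPM). Sums carry exact Poisson intervals and ratios to WT the exact conditional binomial interval of a pair of Poisson counts. A sum of 0 was set to 3 UMIs, giving a lower bound of the fold. To compare shares of cells with a UMI across depths, cells were thinned to 2000 UMIs. No test was run, as each group has 1 library: no p-value, standard error or number of changed genes is given. Summed UMIs of beta-like cells were 91370291 in WT, 101752063 under the label ASF-KO and 86938011 under SC35-KO, so counting error is small for abundant genes and says nothing of the spread between mice.

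Before the data were examined, 34 gene lists were fixed. A member counted as measured at 10 CPM or more in at least 1 of the 2 sums, and lists with under 3 measured members got no median, which left out 7 lists in the comparisons of beta-like cells with WT and 8 in that between the libraries labelled KO. Each median log2 ratio was given relative to that of all genes and placed among 10000 random lists of the same size matched on mean expression in 20 bins. A percentile in the outer 5% (2.5% at each end) is said to stand apart, as a description of these libraries. Members were counted as higher or lower from 1.5-fold relative to the median gene. Percentiles and ratio intervals were tested on simulated counts for the library labelled ASF-KO against WT over 7134 genes. These were independent Poisson draws from the WT profile at the depth of all barcodes. The true fold lay inside the interval for 91.0% of genes changed by 1.5-fold, 95.5% by 2-fold, 98.5% by 4-fold and 95.0% of unchanged genes. Of the lists, 5% of those of unchanged genes and 100% of those changed by 1.5-fold stood apart. The draws hold neither spread beyond counting error nor genes that vary together, so these are no error rates for the real comparisons.

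Genes were named by a rule fixed before the data were examined. In beta-like cells these are the 12 highest and 12 lowest genes against WT, ranked by the bound of the ratio's interval nearest to 1. They need at least 50 CPM and 20 UMIs in at least 1 of the 2 sums. Mitochondrially encoded, sex-linked and ribosomal protein genes and unnamed gene models were left out. So were genes that another class of at least 100 cells holds at over 10 times the CPM in the library where they are higher. Acinar-like cells (19 in WT, 2 labelled ASF-KO and 5 labelled SC35-KO) were too few to be used, so no gene was left out for a high level there. In classes other than beta-like the rule takes 5 genes each way, and from each list 2 to 4 members with the largest and smallest ratio. Srsf1, Srsf2 and islet hormone genes were always included. Some genes that this rule takes are not reported here. Gene positions come from GENCODE vM21 on GRCm38.

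Alternatives were a looser and a stricter cell filter, no doublet removal, Leiden at 0.5 and 2.0, each library clustered on its own, CPM without hormone and mitochondrially encoded genes, median-of-ratios factors, means of per-cell CPM, other minimum levels for list members, and thinning to 4000 UMIs or none. Counting the exocrine-led clusters as beta-like was added after the data were seen.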

Results

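Pancreatic islet cells from mice 9 months old were profiled by single-cell RNA sequencing in 3 genotypes: wild type (WT), ASF-KO and SC35-KO. ASF is an older name of SRSF1 and SC35 of SRSF2, both SR proteins that bind exons in pre-mRNA and help to choose splice sites. The title of the series asks what these proteins do as diabetes develops. Each genotype had 1 library, made from islets that were picked under a microscope and dissociated, with a droplet kit that tags the 3' ends of transcripts and counts molecules by unique molecular identifiers (UMIs). The libraries held 154099078 UMIs in WT, 148320213 under the label ASF-KO and 150116204 under SC35-KO. After the cell filter and removal of doublets, 8913, 7038 and 10744 cells were kept, with medians of 14234, 16887.5 and 9865 UMIs per cell. There were no replicates, so no difference between genotypes could be tested. All intervals are 95% intervals that cover counting error only, and every difference is between libraries.

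The genes named by the labels were read before any other. Srsf1 (ENSMUSG00000018379) lies on chromosome 11 of GRCm38 from 88047373 to 88053755 on the plus strand, and Srsf2 (ENSMUSG00000034120) on the same chromosome from 116849901 to 116853094 on the minus strand. Over all kept cells, Srsf1 stood at 42.8 CPM (UMIs scaled to a common total; 41.7 to 43.9) in WT, at 47.0 (45.9 to 48.2) in the library labelled ASF-KO and at 52.8 (51.5 to 54.0) in the library labelled SC35-KO. Srsf2 stood at 33.6 CPM (32.7 to 34.6), 62.4 (61.1 to 63.8) and 35.8 (34.8 to 36.8) in the same order. In beta-like cells the targeted genes were close to WT. Srsf1 had a ratio to WT of 0.925 (0.884 to 0.969) in the library labelled ASF-KO. Srsf2 had a ratio of 0.948 (log2 of -0.08, with an interval from -0.16 to 0.00) in the library labelled SC35-KO. Both ratios rested on the scaling, since they were 1.25 and 1.30 once hormone and mitochondrially encoded genes were left out of the total, and 1.24 and 1.29 with median-of-ratios factors. The larger difference was in Srsf2 of the library labelled ASF-KO, at 1.88 times WT in beta-like cells (1.80 to 1.97). There it stood at 1.98 times WT in alpha-like, 1.95 in delta-like, 2.12 in gamma-like and 2.36 in endothelial-like cells (1.94 to 2.89), and it was higher under both other scalings too. Srsf1 itself was higher than in WT in alpha-like cells labelled ASF-KO, at 103 against 63.8 CPM, in delta-like cells, at 84.0 against 61.9, and in gamma-like cells, at 39.8 against 25.3 (ratio 1.57, 1.22 to 2.03), while endothelial-like cells stood at 73.7 against 67.8. It was higher in the library labelled SC35-KO too, at ratios of 1.27 in alpha-like, 1.63 in delta-like and 1.56 in gamma-like cells. Endothelial-like cells of the library labelled SC35-KO also held more Srsf2, at 125 against 72.1 CPM.

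With each cell thinned to 2000 UMIs, 9.14% of WT cells, 11.2% of cells in the library labelled ASF-KO and 11.8% of those labelled SC35-KO had an Srsf1 UMI, and 7.96%, 14.1% and 8.75% an Srsf2 UMI. Thinning left out 488, 363 and 487 shallower cells; without it the shares were 44.1%, 54.5% and 44.2% for Srsf1 and 38.2%, 62.8% and 33.6% for Srsf2. Both genes are used by nearly all cell types, so no class here gives a level of free RNA for them. The labels do not say which exons were deleted or in which cells, and 3' tags outside a deleted part check nothing. As neither target was clearly lower, the libraries are named by their labels throughout. Each direction below rests on those labels.

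**Figure D1:**
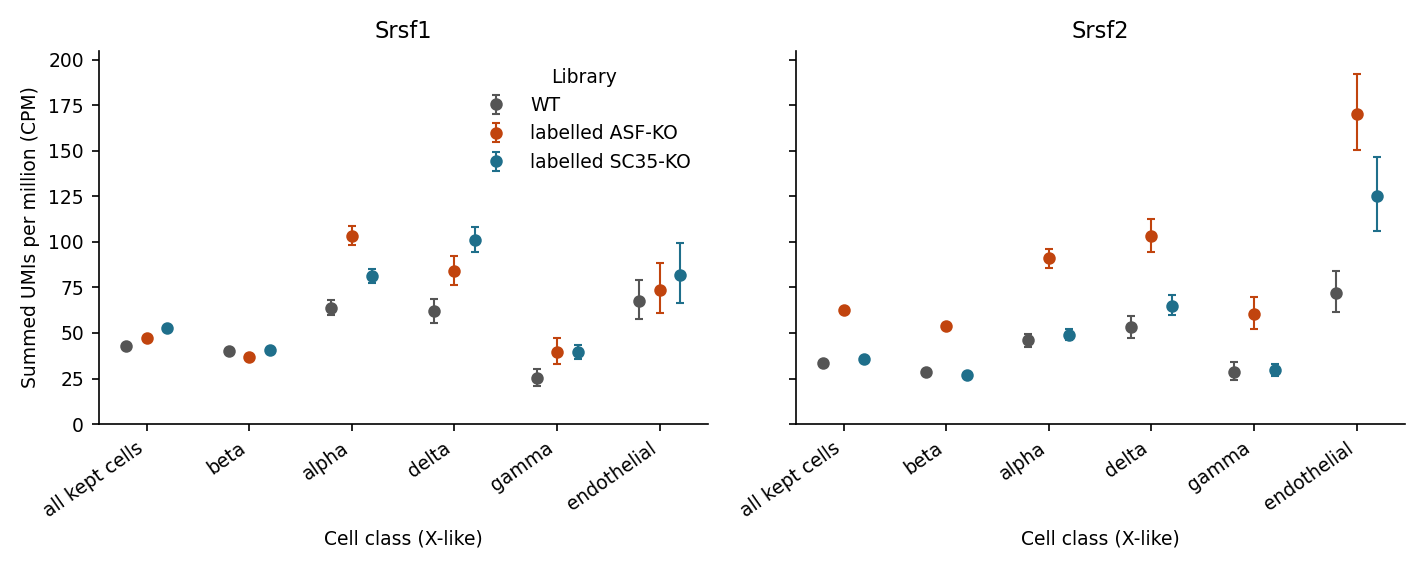
Srsf1 and Srsf2 in CPM of summed UMIs (vertical axis) over all kept cells and in 5 cell classes (horizontal axis), for the 3 libraries; points are values of 1 library each and bars are exact Poisson 95% intervals. Srsf2 lies highest in the library labelled ASF-KO in each class, from 53.9 CPM in beta-like to 170 CPM in endothelial-like cells, while Srsf1 in beta-like cells lies between 37.0 and 40.9 CPM in all 3 libraries.

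The makeup of the islet preparations was compared next. Immune cells were fewer in both libraries labelled KO: they made up 4.98% of kept cells in WT (4.54 to 5.45, exact binomial interval), 0.867% under the label ASF-KO (0.664 to 1.11) and 1.09% under SC35-KO (0.901 to 1.30). Lymphocytes accounted for most of that gap, with 143, 8 and 1 B-like or plasma-like cells and 130, 10 and 10 T-like cells, while macrophage-like cells numbered 134, 39 and 93. Alpha-like cells, the source of glucagon, made up 15.5% of kept cells in WT (14.8 to 16.3), 20.9% in the library labelled ASF-KO (19.9 to 21.8) and 26.2% in the library labelled SC35-KO (25.4 to 27.1). Somatostatin-producing delta-like cells stood at 7.90%, 8.87% and 14.0%, and endothelial-like cells at 7.40%, 6.05% and 3.68%. Among endocrine cells alone, the alpha-like share differed from WT by 3.60 points (2.10 to 5.10) under the label ASF-KO and 6.92 (5.57 to 8.26) under SC35-KO. The delta-like share differed there by -0.275 points (-1.375 to 0.830) and 4.26 (3.21 to 5.29). Ductal-like cells (0.987%, 0.156% and 0.372%), fibroblast-like cells (0.797%, 0.185% and 0.326%) and pericyte-like cells (1.11%, 0.639% and 0.484%) were scarcer in both libraries labelled KO. So were dendritic-like cells (0.415%, 0.0568% and 0.121%) and acinar-like cells (0.213%, 0.0284% and 0.0465%).

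Insulin-producing beta-like cells made up 45.1% of kept cells in WT (44.1 to 46.1), 51.0% in the library labelled ASF-KO (49.8 to 52.2) and 45.1% in the library labelled SC35-KO (44.2 to 46.0). Among endocrine cells alone the shares were 62.6%, 61.5% and 49.0%, a difference of -1.13 percentage points (-2.85 to 0.592, Newcombe interval) for the library labelled ASF-KO and of -13.7 points (-15.2 to -12.1) for the library labelled SC35-KO. Clusters left without a name held 12.5%, 9.19% and 1.92% of kept cells. Among them, cells with beta markers led by exocrine genes and metallothioneins made up 9.24%, 5.06% and 0.177% in the largest cluster. The cell filter removed 9.53% of WT barcodes, 40.8% of those labelled ASF-KO and 16.1% of those labelled SC35-KO. The beta share of the library labelled ASF-KO differed from WT by -7.27 points under a looser filter and by 18.9 under a stricter one, where other clusters were left without a name. Counting each such cluster in the class its markers match best, chosen after the result was seen, gave 9.43 points under the looser filter, shares of 59.3% against 59.1% under the stricter one, and 2.67 points here. For the library labelled SC35-KO it gave -10.6 points here. Among endocrine cells alone, such counting gave -2.78 points (-4.35 to -1.21) here for the library labelled ASF-KO, 3.74 under the looser filter and -4.23 under the stricter one. It gave -18.2 points here for the library labelled SC35-KO. Such a match can rest on free insulin RNA. With the looser filter the differences of the library labelled ASF-KO were 1.25 points for alpha-like and -0.622 for delta-like cells, against 5.33 and 0.968 here. With the stricter filter the immune total differed by -1.20 points under the label ASF-KO and -0.899 under SC35-KO, against -4.11 and -3.89 here, but there a cluster led by immunoglobulin genes (148, 7 and 6 cells) had no name. With it counted the differences were -2.89 and -2.64. The gamma-like share (3.47%, 2.17% and 6.73%) also changed direction between settings in the library labelled SC35-KO.

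**Figure D2:**
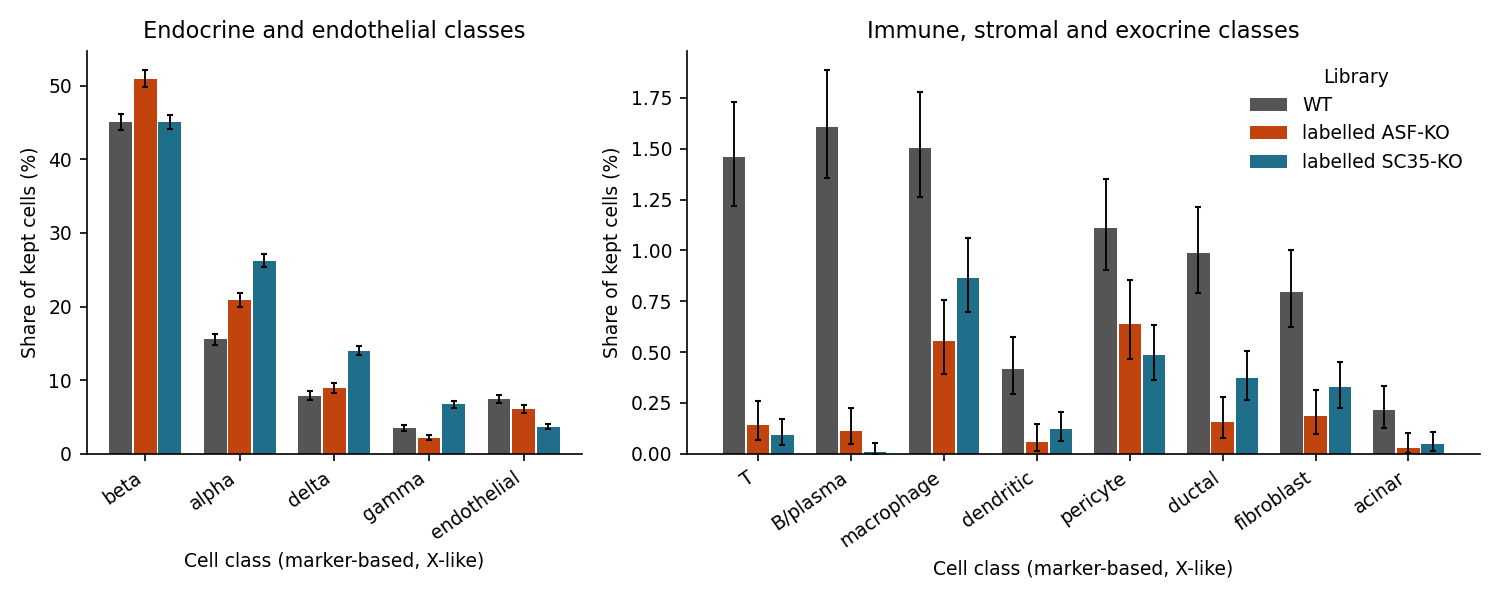
Share of kept cells (percent, vertical axes) in each marker-based class (horizontal axes) for the 3 libraries; bars start at 0 and error bars are exact binomial 95% intervals of 1 library each. Alpha-like cells stand at 15.5% in WT and 26.2% in the library labelled SC35-KO, and T-like and B-like or plasma-like cells stand at 1.46% and 1.60% in WT against at most 0.142% in the others; the beta-like bar of the library labelled ASF-KO (51.0%) lies below WT in some other settings, in which other clusters were left without a name.

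Expression was then compared within beta-like cells, with 4019 cells in WT, 3588 under the label ASF-KO and 4845 under SC35-KO. Insulin transcripts took 52.8% of beta-like UMIs in WT, 63.6% in the library labelled ASF-KO and 63.2% in the library labelled SC35-KO, and the median gene stood accordingly at 0.723 and 0.722 times its WT level (a log2 shift of -0.47 in both). Lists are therefore given relative to this shift, and a gene with a CPM ratio near 0.72 sat at the median. Different clusters held most beta-like cells of each library. A cluster led by Mt2, Mt1, Slc2a2 and Gad1 held 53.9% of those in WT. By contrast, 52.7% of those labelled ASF-KO lay in a cluster led by Sdf2l1, Fkbp11, Creld2 and Hspa5, and 70.3% of those labelled SC35-KO in a cluster led by Nupr1, Ins1 and Iapp. A cluster held mostly by 1 library can be that library rather than a cell state, so only sums over the whole class are compared.

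In beta-like cells of the library labelled ASF-KO, several chaperones of the endoplasmic reticulum (ER) were higher than in WT, and the beta cell identity list had a lower median relative to the shift. Sdf2l1, an ER chaperone component, stood at 174 CPM against 29.8 (ratio 5.84, 5.61 to 6.08), and Hspa5, the main ER chaperone (BiP), at 1063 against 501 (2.12, 2.10 to 2.14). Creld2 (3.64), the disulfide isomerase Pdia6 (2.57) and the secreted stress protein Manf (2.45) were higher as well. Of 19 measured genes of the unfolded protein response, 11 were at least 1.5 times above the shift, 3 at least 1.5 times below it and 5 in between. Their median log2 ratio was 1.21 above the shift (percentile 100 among 10000 random lists matched on expression). The 3 lower members were Chac1 (0.372), which degrades glutathione, the asparagine synthetase Asns (0.427) and the stress-induced transcription factor Ddit3, also called CHOP (0.467).

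Beta cell identity genes had a median log2 of -0.36 relative to the shift in the library labelled ASF-KO (percentile 0.18; 3 of 19 higher by 1.5 times, 2 lower and 14 between). The glucose transporter Slc2a2 stood at 147 against 379 CPM (ratio 0.388, 0.381 to 0.396), and the other lower member was the transcription factor Foxa2 (0.479). The transcription factor Neurod1 stood at 0.492, within 1.5 times of the shift. By contrast, Ins2 stood at 1.24 times WT, Ins1 at 1.10 and Pdx1, which activates insulin transcription, at 1.07. The metallothioneins, small metal-binding proteins, gave the lowest ratios of all genes named in beta-like cells: Mt1 stood at 153 CPM against 5608 (ratio 0.0273, 0.0269 to 0.0277) and Mt2 at 28.0 against 1487 (0.0188, 0.0181 to 0.0195). Their list, oxidative stress defence, nevertheless had a higher median (0.43 above the shift, percentile 99.5; 4 of 14 higher, 2 lower and 8 between), with thioredoxin Txn1 at 1.64 and its inhibitor Txnip at 1.60.

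Mitochondrially encoded genes (median 0.44 above the shift, percentile 98.1; 6 of 13 higher, 1 lower and 6 between) were led by mt-Nd6 (35.5 against 17.8 CPM), while mt-Nd3 stood at 0.309. Immediate early genes (0.44, percentile 97.8; 4 of 9 higher) were led by Jun at 1.82 and Jund at 1.41. Genes of sterol and fatty acid synthesis (0.41, percentile 99.8; 5 of 16 higher) included Idi1 at 1.62 and Cyp51 at 1.53, though the list median was -0.03 among members at 50 CPM or more. Alpha cell identity, with 5 measured members, stood 0.86 above the shift (percentile 99.7, with 3 higher and 2 between), with the thyroxine carrier Ttr at 1.33 and Gcg at 0.798. Free RNA from alpha-like cells, which made up 20.9% of kept cells in this library against 15.5% in WT, was not told apart from it. Exocrine enzymes (0.38, percentile 99.4) turned to -0.03 at a finer clustering and to -0.64 when the exocrine-led clusters were counted as beta-like. The other 19 lists with at least 3 measured members had medians between -0.46 and 0.48 and did not stand apart. Among them, SR proteins stood at 0.27, with Srsf2 at 1.88 and Tra2a at 0.497, and insulin exocytosis at -0.11, with the calcium channel Cacna1d at 0.350. Prohormone processing, at 0.36, held the convertase Pcsk1 at 1.77 and the carboxypeptidase Cpe at 0.547.

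By the fixed rule, 12 genes each way were named for this comparison. Besides those given, the higher genes were the prolyl isomerases Fkbp11 (5.86) and Ppib (2.40), Dapl1 (3.66), the mitochondrial fumarase Fh1 (2.52), the ER chaperone Hyou1 (2.43), cytochrome c (Cycs, 2.11) and the ER selenoprotein Selenok (2.05). Lower genes were T2 (0.201), Cln6 (0.233), Tmsb15b2 (0.249), Dcaf12l1 (0.288), Vldlr (0.309), Grina (0.309), the transcription factor Atf5 (0.314), Zdhhc2 (0.316), Smim4 (0.322) and the defensin Defb1 (0.323). None of these 24 genes changed direction under the other scalings.

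**Figure D3:**
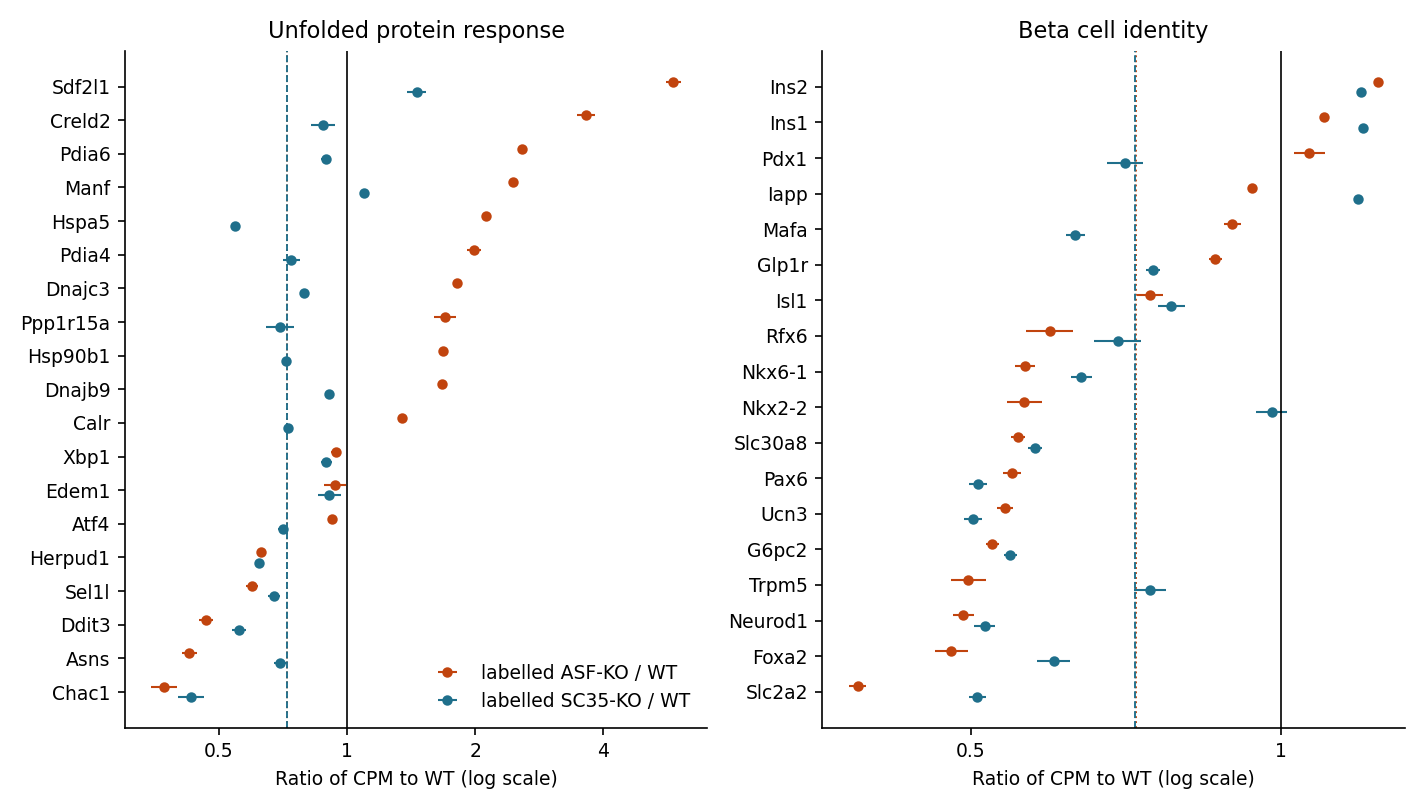
Ratio of CPM to WT in beta-like cells (horizontal axes, log scale) for members of the unfolded protein response list and of the beta cell identity list (vertical axes); points are 1 library against WT, bars are 95% counting intervals, the solid line marks a ratio of 1 and the broken lines the median gene of each comparison (0.723 and 0.722). Sdf2l1, Creld2, Pdia6, Manf and Hspa5 lie above 2 in the library labelled ASF-KO only, whereas Chac1 (0.372 and 0.431) and Slc2a2 (0.388 and 0.507) lie to the left in both.

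In beta-like cells of the library labelled SC35-KO, exocrine enzymes were lower than in WT. Relative to the shift, the heat shock and immediate early lists had lower medians and the ribosomal protein list a higher one, though the immediate early direction turned between settings. All 11 measured exocrine enzymes were lower, with a median log2 of -2.25 relative to the shift (percentile 0), among them Ctrb1 at 6.25 against 52.8 CPM (ratio 0.118, 0.108 to 0.129) and Clps at 0.107. A Ctrb1 UMI was found in 67.7%, 69.0% and 10.3% of beta-like cells (medians of 22548, 27017.5 and 17325 UMIs), and in 60.5%, 74.9% and 10.1% of endothelial-like cells, which lack exocrine enzymes (2971, 3381 and 2531 UMIs), so these shares are at the level of free RNA. Heat shock genes had a median of -0.51 (percentile 0; 3 of 10 lower by 1.5 times, 7 between), with the co-chaperones Dnajb1 at 0.415 and Hsph1 at 0.417. Immediate early genes stood at -0.46 (percentile 0.02; 3 of 9 lower and 6 between), with Klf6 at 0.442 and Junb at 0.450, but turned to 0.24 under a stricter cell filter and 0.09 at a finer clustering.

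Cytosolic ribosomal proteins stood 0.43 above the shift in the library labelled SC35-KO (percentile 99.95; 4 of 22 higher and 18 between), with Rpl23 at 1.11 and Rpl3 at 0.737. Nuclear-encoded oxidative phosphorylation (0.28, percentile 99.3; 1 of 28 higher, 1 lower) included Ndufa4 at 1.08 and Atp5k at 0.427, and SR proteins (0.27, percentile 99.5; 1 of 12 higher) ranged from Srsf9 at 1.35 to Tra2a at 0.567. The list of insulin exocytosis and electrical activity had a lower median (-0.23, percentile 0.13; 2 of 21 lower and 19 between), with Cacna1d at 0.414 (0.401 to 0.428), Exph5 at 0.464 and the granule protein Sytl4 at 0.482. The NF-kB list (-0.34, percentile 1.19) had 4 measured members, all within 1.5 times of the shift, with Nfkbia at 0.540 and Nfkb1 at 0.760. Sterol synthesis (0.19, percentile 97.9; Insig1 at 1.57) turned to -0.06 among members at 50 CPM or more, and alpha cell identity (0.51, percentile 98.2; Gcg at 1.47, Pcsk2 at 0.473) to -0.32 when the exocrine-led clusters were counted as beta-like. Alpha cell identity also stood at 0.42 in endothelial-like cells of this library, which make no glucagon, with Gcg at 7245 against 2247 CPM there and at 1123 against 763 in beta-like cells.

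The unfolded protein response (0.01, percentile 38.7) and beta cell identity (-0.06, percentile 10.5) did not stand apart in the library labelled SC35-KO, although Hspa5 stood at 0.548 and Sdf2l1 at 1.46, and Ucn3, a peptide hormone of mature beta cells, at 0.502 and Slc2a2 at 0.507 against Ins1 and Ins2 at 1.20. Counting members at 50 CPM or more alone, beta cell identity did stand apart at -0.17. The other 15 lists lay between -0.25 and 0.20. Genes named by the rule as higher were Pappa2, a protease of insulin-like growth factor binding proteins (3.43, 3.25 to 3.61), Dapl1 (2.33), the transcription factor Etv1 (1.68), Nupr1 (1.57), Insig1, Srp9 (1.41), Ssr4 (1.39), Arf5 (1.33), Kdelr2 (1.32), Fuom (1.31), Bex4 (1.29) and Ost4 (1.29). The lower ones were Mt2 (0.227), Sox4 (0.305), Mt1 (0.320), Lars2 (0.334), Nmt1 (0.351), the GABA-synthesising enzyme Gad1 (0.369), T2 (0.407) and Ttc28 (0.414), together with Ctrb1, Cacna1d, Dnajb1 and Hsph1. Pappa2 was among the 10 leading genes of both clusters of alpha-like cells, which made up 26.2% of kept cells in this library against 15.5% in WT. Free RNA from alpha-like cells was not told apart from its rise.

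**Figure D4:**
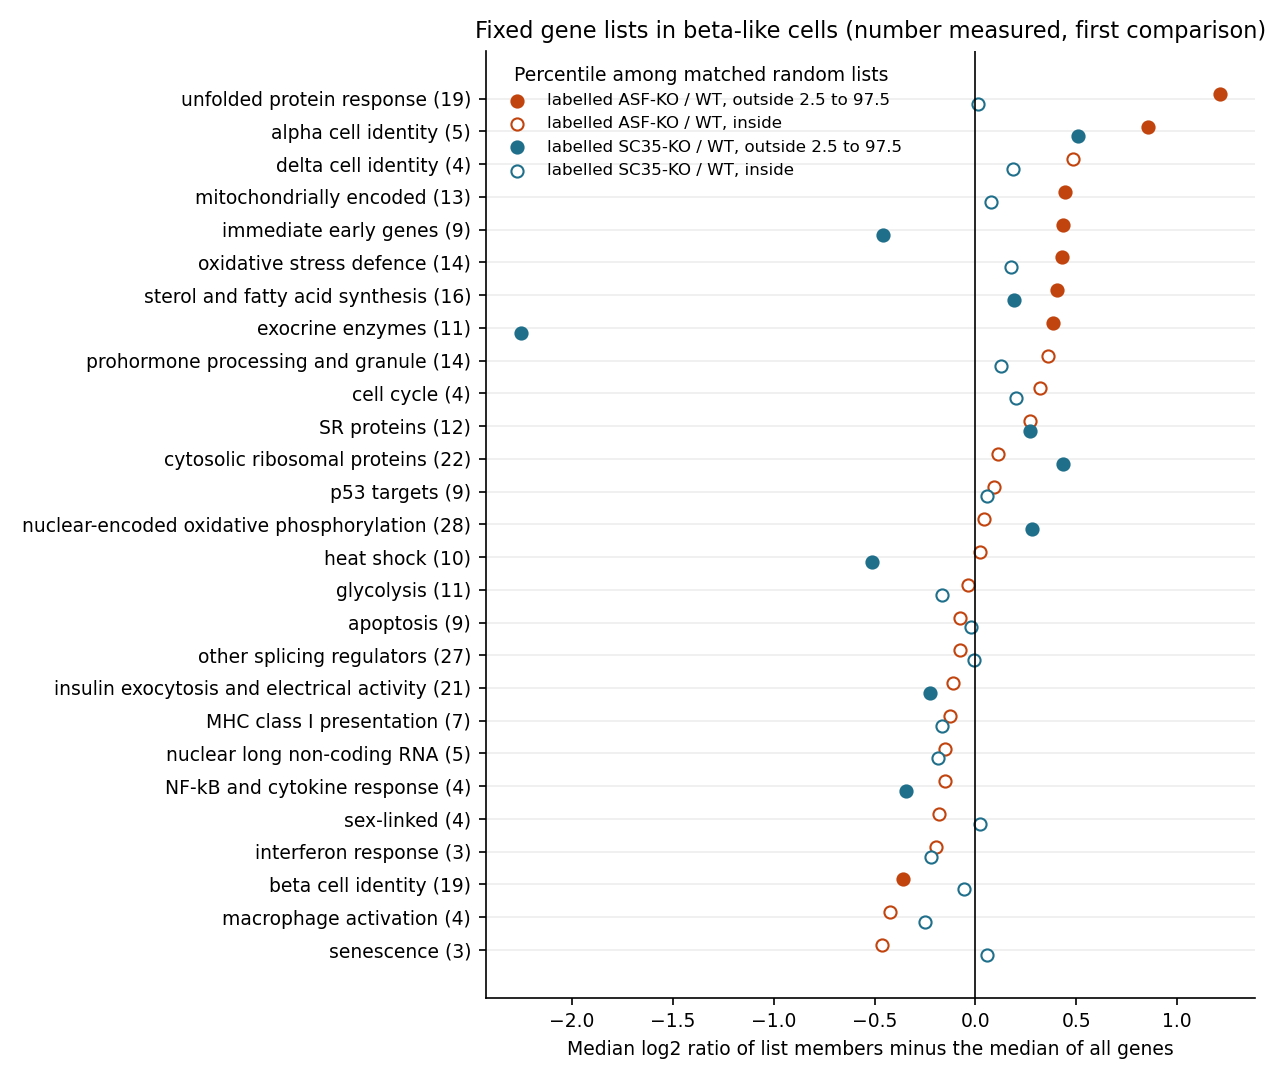
Median log2 ratio of the measured members of each fixed gene list in beta-like cells, minus the median of all genes (horizontal axis), for both comparisons with WT; filled points lie in the outer 5% of 10000 matched random lists. The unfolded protein response lies at 1.21 for the library labelled ASF-KO and at 0.01 for the library labelled SC35-KO, and exocrine enzymes at 0.38 and -2.25, of which the former turns negative under 2 alternatives.

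Outside beta-like cells, 4 classes held at least 100 cells in each library, and the median gene lay between -0.20 and 0.16 log2 units of WT. Mitochondrially encoded genes were higher in all of them in the library labelled ASF-KO, with medians of 0.76 in alpha-like, 0.61 in delta-like, 0.55 in gamma-like and 0.39 in endothelial-like cells, and in alpha-like cells mt-Nd6 stood at 3.60, mt-Nd5 at 2.59 and mt-Nd3 at 0.499. Nuclear-encoded oxidative phosphorylation was lower there (-0.29, -0.38, -0.29 and -0.44), with Atp5k at 0.358 and Atp5e at 0.569 in alpha-like cells. Genes about as short as Mt2 (511 nt) were lower in the same classes, with medians of -0.69, -0.65, -0.76 and -0.91. Sterol and fatty acid synthesis was higher in the same classes (0.40, 0.50, 0.60 and 0.74), and Cyp51 stood at 2.48 in alpha-like cells. The unfolded protein response stood at -0.05 in alpha-like, -0.00 in delta-like and 0.09 in endothelial-like cells, where it did not stand apart, and at 0.35 in gamma-like cells (percentile 99.96). Whether it differed between classes was not tested. Heat shock genes were lower in alpha-like (-0.50), gamma-like (-0.76) and endothelial-like cells (-0.71), with the small heat shock protein Hspb1 at 0.251 in alpha-like cells.

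Alpha-like cells of the library labelled ASF-KO held more Lgi2 (ratio 4.22, 3.58 to 4.99), Hist1h1e (3.44), Upk3a (2.81), Hapln1 (2.75) and Zim1 (2.68) than WT, and less Mt2 (0.0428), Mt1 (0.0585) and the tetraspanin Cd9 (0.239). Delta-like cells held more Zim1 (3.71, 2.92 to 4.76) and the phosphodiesterase Pde10a (3.12), and less Mt1 (0.121), Ppp1r17 (0.189), Bc1 (0.304) and Atp5k (0.327). Their haemoglobin genes Hbb-bs, Hba-a1 and Hba-a2 were also higher, but 10 cells held at least 99.8% of those UMIs. Gamma-like cells differed in makeup, with Ins2 at 88826 CPM in WT, 217250 under the label ASF-KO and 284450 under SC35-KO. Their other named genes in the library labelled ASF-KO were Sdf2l1 (4.04), Wnk3 (3.43), Ckb (3.31) and Mrps28 (3.08) as higher, and Mt2 (0.0608), Mt1 (0.0666), Bc1 (0.258) and Atp5k (0.339) as lower.

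Exocrine enzymes and heat shock genes were lower in the other classes of the library labelled SC35-KO as well, with medians of -2.36 and -0.83 in alpha-like, -2.17 and -0.65 in delta-like, -3.05 and -0.83 in gamma-like and -2.36 and -0.62 in endothelial-like cells. In its alpha-like cells Dnajb1 stood at 103 against 425 CPM (ratio 0.241, 0.230 to 0.253), and Ctrb1 (0.135), Cela3b (0.148) and Prss2 (0.173) were lower, while Upk3a (2.64), Pcsk2os1 (1.73), Yipf4 (1.70), the actin-binding peptide Tmsb4x (1.64) and Ost4 (1.54) were higher. Immediate early genes were lower in alpha-like (-0.78), delta-like (-1.03) and gamma-like cells (-1.29), with Klf6 at 0.345 and Fos at 0.466 in alpha-like cells, and higher in endothelial-like cells (0.19). Delta-like cells held more Slc24a5 (3.87, 3.03 to 4.98), Hnf1aos1 (3.27), Hypk (2.05) and Spock3 (1.97), besides Hbb-bs from few cells (10 cells held 98.9% of its UMIs), and less Clps (0.159), Ctrb1 (0.163), Cpa1 (0.191), Cela3b (0.203) and Try4 (0.223). In gamma-like cells Nupr1 (3.92), Iapp (3.33), Ins2 (3.20), Pcsk1 (2.89) and Ins1 (2.88) were higher, of which Nupr1 and Ins1 turned lower at other cluster resolutions, and Ctrb1 (0.113), Bc1 (0.255), Lars2 (0.284), Dnajb1 (0.285) and Hspa1a (0.300) were lower.

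Endothelial-like cells of the library labelled ASF-KO held more Dbp and Tef, transcription factors that follow the circadian clock, than WT (Dbp at 158 against 24.6 CPM, ratio 6.43, 4.80 to 8.74; Tef at 61.5 against 14.7, ratio 4.19, 2.81 to 6.39). Mxra7 (6.80), the Wnt inhibitor Sost (5.81) and the glycolysis regulator Pfkfb3 (3.96) were higher too. Mt2 (0.0278), Mt1 (0.0563) and Lrg1 (0.0630) were lower, but 10 cells of WT held 43.8%, 48.5% and 69.9% of their UMIs. The chemokine Ccl21a (at least 127-fold lower) and Ubd (at least 30.8-fold lower), with 0 UMIs, came from 6 and 2 cells of WT. Endothelial activation genes did not stand apart, with Vwf, a clotting factor carrier, at 0.158 and the growth factor receptor Flt1 at 1.45. Most Vwf lay in a cluster led by Ccl21a at resolution 2.0, with 44 cells in WT, 8 labelled ASF-KO and 34 labelled SC35-KO. Without it, a check made after the values were seen, 11 Vwf UMIs were left in WT and 2 under the label ASF-KO (ratio 0.251, 0.0271 to 1.15), and Lrg1 stood at 0.921, while Dbp stood at 6.31. In the library labelled SC35-KO, endothelial-like cells held more of the endothelial transcription factor Sox18 (614 against 212 CPM, ratio 2.90, 2.58 to 3.25), of Zfp36, which speeds mRNA decay (2.63), of Maf (52.6 against 13.8 CPM; 68.3% of UMIs in 10 cells) and of Gng2 (3.41). Haemoglobin Hbb-bt (7.56) rested on 3 cells, and Clps (0.0769), Ctrb1 (0.149), Cpa1 (0.160), Ccl21a and Ubd were lower.

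Most alpha-like cells of the library labelled SC35-KO (2729 of 2819) lay in another cluster than most of those in WT (916 of 1384) or labelled ASF-KO (1281 of 1468). Ghrl, the hormone of epsilon cells, stood at 577 CPM in alpha-like cells of WT against 0 in the library labelled ASF-KO (at least 2640-fold lower, counting 0 as 3 UMIs) and 4.79 in the library labelled SC35-KO. It rested on 1 cell, which held 8136 of the 8461 kept UMIs in WT. In the library labelled SC35-KO 2 Ghrl-rich barcodes were not kept, and with a looser filter Ghrl was higher there (log2 ratio 6.10).

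Finally, the libraries labelled KO were set against each other. The unfolded protein response was lower in beta-like cells of the library labelled SC35-KO than in those labelled ASF-KO (median log2 of -0.87 relative to all genes, percentile 0; 11 of 19 lower, 1 higher and 7 between), as were immediate early genes (-1.09), exocrine enzymes (-2.82), heat shock genes (-0.53) and prohormone processing (-0.52). Senescence, with 3 measured members, was higher (0.60, percentile 98.3), and the other lists did not stand apart. Log2 ratios to WT of 1575 genes had a Pearson r of 0.509 across genes, which are not replicates. Unchanged counts set against the same WT sum gave 0.508, so r says little here; the covariance was 0.104 against 0.000269 for unchanged counts, a difference of 0.104. With WT cells split in 2 the values were 0.510 and 0.104, but both parts come from 1 library, so some or all of the covariance can be particular to it. Among the genes named for both comparisons, those lower than WT in both libraries included Mt1, Mt2 and T2, and Dapl1 was higher in both.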

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

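Both tests of the Srsf2 pattern, the test of cells from outside the islets and all tests of free RNA were chosen after the result was seen; the filter test and the length test were set before, and in those the marker set, the lowest expression level and a window around Mt2 alone were revised after a first run. The bounds for cells from outside the islets and for free RNA were made stricter after their values were seen. Under the earlier bounds the values had counted in favour of cells from outside the islets and of free RNA in endothelial-like cells, and against free RNA in gamma-like cells; all of these are left open here. Some lists stood apart in opposite directions between cell classes, and those differences were not tested. In the library labelled SC35-KO, alpha cell identity stood at 0.51 in beta-like, 0.42 in endothelial-like and -0.46 in gamma-like cells, and beta cell identity at -0.19 in delta-like, -0.66 in endothelial-like and 0.63 in gamma-like cells. Its immediate early genes stood at -0.78 in alpha-like, -0.46 in beta-like, -1.03 in delta-like and -1.29 in gamma-like cells, against 0.19 in endothelial-like cells. In the library labelled ASF-KO, beta cell identity stood at -0.36 in beta-like, -0.91 in endothelial-like and 0.20 in gamma-like cells, and prohormone processing at -0.48 in endothelial-like and 0.26 in gamma-like cells. Endocrine transcripts in endothelial-like cells can be free RNA, and gamma-like cells differed in makeup between libraries. Several of these medians in endothelial-like and gamma-like cells changed direction in other settings, and that of beta cell identity in delta-like cells did so once (0.0844 among members at 50 CPM or more).

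Srsf2 was higher in the library labelled ASF-KO than in WT in all 5 classes compared. Scaling by totals in which insulin takes a larger share would lower Srsf2, not raise it, so this test could hardly have favoured that explanation. In beta-like cells its ratio was 2.55 without hormone and mitochondrially encoded genes, against 1.88 by CPM. The smallest lower bound of its log2 ratio was 0.62 over the 5 classes with the other scalings. Swapped labels need a lower Srsf1 in the library labelled SC35-KO, where it stood at 1.02 times WT in beta-like cells (0.976 to 1.07; 1.40 without hormone and mitochondrially encoded genes) and at 1.27, 1.63 and 1.56 in alpha-like, delta-like and gamma-like cells, but they stay open, as 3' tags need not show a deletion and neither target was clearly lower under its own label. If SRSF1 is missing in these cells, a rise of Srsf2 might be a response of SR proteins that regulate each other, which full-length reads across the exons of both genes in replicate animals would test.

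Lymphocytes were nearly absent from both libraries labelled KO. Removal by the cell filter is excluded, as barcodes with T or B markers made up 4.55% of all deposited barcodes in WT, against 0.232% under the label ASF-KO and 0.402% under SC35-KO. More cells from outside the islets in the WT preparation stay open: all 6 of 6 differences in ductal-like, acinar-like and fibroblast-like cells also lay below 0, but Ctrb1 in endothelial-like cells, a measure of free exocrine RNA, stood at 404 CPM under the label ASF-KO and 39.2 under SC35-KO against 263 in WT. An effect of genotype on immune cells in the islets is also open and untested. Staining of intact islets for CD3 and B220 in several animals of each genotype would tell these apart.

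Mt1 and Mt2 were lower in the library labelled ASF-KO in all 5 classes. Both were lower than in WT in the library labelled SC35-KO too, by less, so WT held the most in each class. There Mt1 stood at 1796 CPM against 5608 in beta-like, 486 against 1151.5 in alpha-like and 373 against 696 in delta-like cells. In gamma-like cells it stood at 1505 against 2403, and in endothelial-like cells at 241 against 740. The length test was run for the library labelled ASF-KO alone. Length was that of the longest annotated transcript, 1085 nt for Mt1 and 511 nt for Mt2. In beta-like cells 360 genes within 150 nt of either had a median log2 of 0.14, but most of these are not as short as Mt2. The 87 genes within 150 nt of Mt2 had a median of -0.35. None of the 360 lay as low as Mt1 (-4.73), the lowest being -2.13, so loss of short transcripts cannot be the whole cause in these cells. A part of it could be such a loss, since genes as short as Mt2 (511 nt) had medians of -0.35 in beta-like, -0.69 in alpha-like, -0.65 in delta-like, -0.76 in gamma-like and -0.91 in endothelial-like cells. Free RNA from beta-like cells as the whole source is excluded in alpha-like and delta-like cells. Their ratio of Mt1 to Ins2 was at least 1.83 times that of endothelial-like cells (lowest bound over the 3 libraries, with and without the 10 cells that held most Mt1). Free RNA stays open in gamma-like cells, where that bound was 0.76, and in endothelial-like cells. The ratio in endothelial-like cells was 0.99 times that of beta-like cells in WT (1.55 without 10 cells that held 48.5% of Mt1). Under the label ASF-KO it was 2.12 times (1.63 to 2.70), and 1.27 times (0.868 to 1.79) without the 10 cells that held most Mt1. Genotype, and zinc, glucocorticoid or handling of the WT animal or animals, stay open. Measuring both genes in islets of several animals per genotype would test this.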

How the results depend on the processing

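Counting the exocrine-led clusters as beta-like, counting each unnamed cluster in the class its markers match best, and all alternatives for lists outside beta-like cells or between the libraries labelled KO were chosen after the result was seen; the other alternatives were set before the data were examined. No paired analysis was possible because all 3 samples carry replicate number 1 and no test was run, and no library could be left out with 1 per group. Gene ratios and shares counted as the same inside the counting interval of the main result. They counted as reversed if the direction changed and that interval left out equality with WT, and otherwise as moved. Of 1405 gene log2 ratios over the alternatives, 1082 were the same, 316 moved and 7 reversed. Of 629 list medians of beta-like cells against WT, 573 were the same, 26 were stronger, 23 weaker and 7 reversed. For 2929 other list medians the numbers were 2702, 105, 99 and 23. Of 298 share differences, 222 were the same, 63 moved and 13 reversed. All 12 shares of cells with a UMI under other thinning moved. As list medians are relative to all genes, other scalings of the totals could change them only through the minimum level and the matched draws. Counting exocrine-led clusters as beta-like could not change comparisons with WT in other classes. Such alternatives raise the numbers that were the same. The unfolded protein response in beta-like cells of the library labelled ASF-KO lay between 0.97 and 1.22 in all settings, and beta cell identity between -0.38 and -0.29. Without hormone and mitochondrially encoded genes, the log2 ratio of Srsf1 in beta-like cells of the library labelled ASF-KO was 0.32 and that of Srsf2 in the library labelled SC35-KO 0.38. With median-of-ratios factors they were 0.32 and 0.37, and Srsf2 stood at 0.0459 with means of per-cell CPM. At resolution 0.5, Ins1 (-0.35) and Nupr1 (-0.52) turned lower in gamma-like cells labelled SC35-KO, whose share of endocrine cells differed by -0.712 points and whose library's beta share by 1.49. At resolution 2.0 these were -0.23, -0.40, -1.09 and 3.61; its immediate early genes stood at 0.0928, and under the label ASF-KO Srsf1 was at -0.00888, exocrine enzymes at -0.0270, the beta share at -7.00 points and the endocrine total at -2.10. With each library clustered on its own, the beta share differed by -3.86 (ASF-KO) and -5.24 points (SC35-KO), and under ASF-KO the endocrine total by -1.83 and the immune total by -5.18, where its cluster of 61 immune cells had no name (-4.32 by best match). With exocrine-led clusters as beta-like, the beta share differed by 0.877 and -10.1 points, exocrine enzymes stood at -0.64 (ASF-KO) and alpha cell identity at -0.32 (SC35-KO). Among members at 50 CPM or more, sterol synthesis stood at -0.0320 and -0.0604, and beta cell identity under SC35-KO at -0.17. With the looser filter, shares under ASF-KO differed by 1.25 (alpha), -7.27 (beta), -0.622 (delta) and -8.20 points (endocrine total), those under SC35-KO by -1.70 (beta), -0.290 (gamma) and -0.902 (gamma of endocrine cells), and Ghrl in alpha-like cells stood at 6.10. With the stricter filter, the beta share differed by 18.9 and 7.32 points, the immune total by -1.20 and -0.899, alpha of endocrine cells under ASF-KO by -0.637 and gamma under SC35-KO by -0.107, and immediate early genes under SC35-KO stood at 0.24; the lymphocyte cluster had no name there, and by best match the immune total differed by -2.89 and -2.64. Lists outside beta-like cells reversed as follows. In endothelial-like cells, with means of per-cell CPM, prohormone processing stood at 0.0280 (ASF-KO) and 0.13 (SC35-KO), and under SC35-KO beta cell identity at 0.0706 and insulin exocytosis at 0.0327. With each library clustered on its own these were 0.12, 0.38, 0.12 and 0.15. In the same class labelled SC35-KO, insulin exocytosis stood at 0.17 among members at 50 CPM or more, alpha cell identity at -0.0463 with the looser filter and beta cell identity at 0.10 with doublets kept. In gamma-like cells labelled SC35-KO, beta and delta cell identity stood at -0.0169 and -0.0673 with the looser filter, -0.13 and -0.0813 at resolution 0.5, -0.0346 and -0.0674 at resolution 2.0 and -0.0887 and -0.49 in libraries clustered alone, and alpha cell identity at 0.24 with the stricter filter and 0.21 with doublets kept. With doublets kept, beta cell identity in gamma-like cells labelled ASF-KO stood at -0.13, and among members at 50 CPM or more that in delta-like cells labelled SC35-KO at 0.0844. Several shifts in shares come from clusters left without a name. By best match the beta share under SC35-KO differed by -10.6 points (main clustering) to -4.83, and under ASF-KO by 2.67 points in the main clustering, at most 9.43, and 59.3% against 59.1% with the stricter filter. The endocrine total under ASF-KO then differed by 6.02 to 8.56 points, and alpha of endocrine cells with the stricter filter by 4.79. With the looser filter, 1480 alpha-like and 611 delta-like cells labelled ASF-KO were much the same in number as in the main clustering (1468 and 624), but kept cells numbered 9243 against 7038, so their shares moved with the total. The cause of the shifts in gamma shares was not tested. The shares of beta-like and gamma-like cells, the endocrine total, the alpha and delta shares under ASF-KO and the size of the immune gap thus depend on filter, clustering or naming.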

Other observations

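Nr1d1 and Arntl, Aldh1a3 in each class, and Atp5k and Atp5e in classes where the rule did not name them were chosen after their values were seen, as were the comparisons below. Aldh1a3, a retinaldehyde dehydrogenase known as a marker of dedifferentiated beta cells, stood at 2.25 CPM in beta-like cells of WT, at 18.6 in those labelled ASF-KO (ratio 8.25, 7.14 to 9.57) and at 16.4 in those labelled SC35-KO (7.26, 6.27 to 8.44). It was spread over beta-like cells, as 10 of them held 17.5%, 8.45% and 5.41% of its UMIs. The ratios were 40.1 (6.62 to 1640) and 57.9 (10.2 to 2300) in gamma-like cells, with 1 UMI in WT, 3.39 (1.41 to 9.35) and 4.04 (1.81 to 10.6) in alpha-like cells, with 7 UMIs in WT, and 2.83 (1.84 to 4.44) and 1.20 (0.762 to 1.93) in delta-like cells. In gamma-like cells, 10 cells held 88.9% of its UMIs under the label ASF-KO and 34.1% under SC35-KO. Insulin transcripts took 11.6% of gamma-like UMIs in WT, 28.0% under the label ASF-KO and 36.1% under SC35-KO, so this class differed in makeup. In endothelial-like cells Aldh1a3 stood at 2.16, 2.56 and 5.84 CPM. In beta-like cells the direction was the same under the other scalings. The other genes of its fixed list that were looked up after its value was seen went different ways in beta-like cells. All of them lay below the 10 CPM needed to count as measured, so they say little. Gast stood at 0.547, 1.11 and 1.32 CPM, Cck at 0.0109, 0.108 and 0.414 (1, 11 and 36 UMIs, in 1, 6 and 5 cells), Neurog3 at 1.53, 0.924 and 1.63 CPM, Ldha at 0.383, 0.0688 and 0.0805, and Sox9 at 0.0876, 0.0491 and 0.0460. Only 2 genes of that list were measured well enough there, so it had no median.

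In the library labelled ASF-KO, 4 genes tied to the circadian clock differed from WT in ways that varied between classes; they are no fixed list and no test was run on them. In endothelial-like cells Dbp (6.43), Tef (4.19) and the repressor Nr1d1 (2.79, 2.27 to 3.43) were higher than in WT, and the activator Arntl was lower, with 1 UMI (ratio 0.0309, 0.000767 to 0.181). In beta-like cells Dbp (0.410), Tef (0.499) and Nr1d1 (0.284) were lower, while Arntl at 0.791 lay above the median gene (0.723) and stood at 1.07 (0.861 to 1.33) without hormone and mitochondrially encoded genes. In delta-like cells Dbp (0.317), Tef (0.641) and Nr1d1 (0.441) were lower and Arntl higher (3.06, 1.69 to 5.82). Alpha-like cells held more Dbp (1.79), Tef (1.92) and Nr1d1 (2.31), with Arntl at 0.992, and gamma-like cells had ratios of 1.01 for Dbp, 1.54 for Tef (1.12 to 2.13), 0.979 for Nr1d1 and 0.515 for Arntl (0.212 to 1.13). In beta-like, alpha-like, delta-like, gamma-like and endothelial-like cells of the library labelled SC35-KO, Dbp stood at 0.791, 1.05, 1.25, 1.85 and 0.678, Tef at 0.590, 1.08, 1.09, 1.56 and 1.70, Nr1d1 at 0.718, 0.699, 1.40, 1.41 and 0.992, and Arntl at 1.10, 1.03, 1.66, 0.442 and 0.765. The time of day at which islets were taken is not given in the labels.

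Some short transcripts were lower in the library labelled ASF-KO in all 5 classes. The ATP synthase subunit gene Atp5k stood at 0.338 in beta-like, 0.358 in alpha-like, 0.327 in delta-like, 0.339 in gamma-like and 0.374 in endothelial-like cells, and Atp5e at 0.441, 0.569, 0.524, 0.551 and 0.507 in the same order. Atp5k was lower in the library labelled SC35-KO too, at 0.427, 0.459, 0.456, 0.417 and 0.478. There Atp5e stood at 0.733 in beta-like cells, close to the median gene (0.722), and at 0.798, 0.833, 0.698 and 0.852 in the others. In the library labelled ASF-KO, genes as short as Mt2 had negative medians in all 5 classes, and Atp5k and Atp5e are members of the oxidative phosphorylation list.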
